A study of Homo sapiens with 6 samples.

How the data were processed

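Messenger RNA of NCI-N87 cells, an established human gastric carcinoma line, was measured by sequencing of total RNA in 6 libraries. The labels place 2 libraries in each of 3 groups: wild type (WT), and KRT17 knockout groups named KO1 and KO2. The labels do not say whether the numbers in KO1 and KO2 stand for guides or for clones, nor whether the replicates came from separate cultures. The p-values below therefore measure the spread between these libraries, which may be technical.

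Each of the 6 deposited files holds FPKM values (fragments scaled by exon length and library depth) for 58735 Ensembl gene IDs, which the authors computed before deposit. Per the submitters' processing notes, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used with the hg38 genome build. The role of each tool, the strand setting, the handling of reads that map to several places and the annotation release are not given in the sources used here. All 58735 IDs were found in GENCODE release 29, which supplied biotypes, exon lengths and GRCh38 coordinates, and 58207 had a current gene symbol.

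In each deposited FPKM file, the value of a gene multiplied by its union exon length was a whole multiple of one step per library for 100% of values (tolerance 0.1 of a step), so read numbers were recovered. The recovered totals were 22852340 and 19618509 reads in WT replicates 1 and 2, 22673871 and 21880796 in KO1, and 18627054 and 17599759 in KO2. The denominator of the FPKM values was 0.936 to 1.05 times the recovered total, so the values contain a scale factor per library that no source used here describes. At these depths 1 read in a gene of 1 kb equals 0.0429 to 0.0544 FPKM. A fold against a group with 0 reads in all its libraries was computed against a floor of 3 reads per library and written as "at least". Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

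Replicate pairs were compared by a chi-square over genes with at least 20 reads. The value per degree of freedom was 2.46 in WT, 1.80 in KO1 and 2.40 in KO2, which is above counting error. Duplicated reads alone can raise it, so it does not show separate cultures, and each library was counted as a replicate because the labels number it so. Between KO1 and KO2 libraries it was 24.5 to 25.3, and between WT and knockout libraries 309 to 357.

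The design fixed before the data were examined named a count test, and a limma test where the files hold no counts. The files held FPKM, so the limma test was used. Genes with at least 1 FPKM in 2 or more libraries were kept (16046 genes), and log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (group means, mean-variance trend, all 6 libraries, no covariate). Contrasts were the average of KO1 and KO2 minus WT, KO1 minus WT, KO2 minus WT and KO2 minus KO1. Calls were made at a Benjamini-Hochberg adjusted p below 0.05. Fold changes named log2 are on the log2(FPKM + 1) scale, which understates the change of low genes, and are given ± SE. Levels are mean FPKM ± SD of the 2 libraries of a group, and the ratio of such means is called a fold.

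Gene lists (36) were written beforehand from general knowledge: simple keratins, stratified keratins, adherens and tight junctions, desmosomes, matrix adhesion, mesenchymal genes, YAP/TAZ targets, Hippo pathway, IL6/JAK/STAT3, NF-kB and inflammation, interferon response, gastric lineage, intestinal lineage, stem and progenitor markers, squamous differentiation, G1/S, G2/M, p53 targets, unfolded protein and ATF4 response, heat shock, hypoxia and glycolysis, cholesterol synthesis, nuclear respiratory chain, mitochondrially encoded mRNAs, ribosomal proteins, histones, immediate early genes, ERBB receptors and ligands, TGF-beta response, Wnt response, antigen presentation, xenobiotic and NRF2 response, and markers of fibroblasts, leukocytes, endothelium and neuroendocrine cells. Lists with 5 or more tested members (33) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation per list and fry were alternatives.

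Genes are named by a rule fixed beforehand. It takes 10 genes whatever their values (KRT17, CDH1, YAP1, WWTR1, IL6, CCN1, CCN2, ANKRD1, VIM, STAT3). It adds the 10 highest and 10 lowest protein-coding fold changes of the knockout average that were called the same way in both groups with a mean of at least 1 FPKM in WT or in the knockout libraries. It adds the 5 highest and 5 lowest for KO2 minus KO1, and up to 4 members per list with the smallest adjusted p. Some multigene family members, histones among them, are named only as uncertain. Others, such as IFITM1, RPL19, RPL23 and several keratins, are named without that mark, and their reads may be shared with related copies. Y-linked genes and XIST are not named. Some genes that the rule selects are not reported here. Genes outside the rule are marked as chosen after their values were seen.

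The limma script was tested on simulated values for the 16046 genes with the spread of the real libraries. Changed genes were drawn only from those with a mean log2 level above 2, and the other genes were left unchanged. Noise was independent between genes. Recovery of changes in lower genes was therefore not tested. Only 67, 67 and 66 genes were changed by 1.5-, 2- and 4-fold, a far smaller share than was called in the real libraries. Recovery and false calls with most genes changed were not tested. For the knockout average the script recovered 91.0% of changes of 1.5-fold, 97.0% of 2-fold and 97.0% of 4-fold, with 10 false calls. For KO1 and for KO2 against WT it recovered 83.6% of 1.5-fold changes, with 8 false calls each, and for KO2 against KO1 it made 0 false calls. For the knockout average, a simulated list shifted by 0.5 log2 units was called, and 0 of 35 unshifted lists were. This does not cover lists whose genes are correlated.

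Alternatives fixed beforehand were quantile normalization, library size as the only scaling, no filter, a filter of 5 FPKM, a pseudocount of 0.1, each library left out, the replicate number as a block, only the 4 libraries of the groups compared, both knockout groups as one group of 4, and a test against a fold of 1.5. limma voom on the recovered reads was added after the data were examined. With library size as the only scaling, the median of all genes for the knockout average moved from 0.02 to 0.14 log2 units, and with voom to 0.17. Neighbouring genes were scanned, also chosen after the data were examined, as medians of windows of 25 of the 11852 tested protein-coding genes on 23 chromosomes, after centring on the median of all, and compared with 1000 shuffles of gene positions (200 for the differences between replicates) in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1).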

Results

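Total RNA of 6 NCI-N87 libraries was sequenced, 2 from wild-type cells and 2 from each of the KRT17 knockout groups KO1 and KO2. NCI-N87 is a gastric carcinoma line known for amplification of ERBB2, the gene of the HER2 receptor. The series title places keratin 17, YAP, IL6 and E-cadherin on one axis in diffuse gastric cancer, and the libraries address which transcripts differ when KRT17, an intermediate filament gene of stressed and stratified epithelia, is targeted. The recovered depth was 17599759 to 22852340 reads per library. Between 13608 and 14133 genes per library reached 1 FPKM.

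KRT17 itself (ENSG00000128422, GRCh38 chromosome 17, 41619441 to 41624842) was at 746 ± 10.1 FPKM in WT, 2.35 ± 0.0823 in KO1 and 10.9 ± 0.660 in KO2 (SD, n = 2 each). It kept 0.314% of its WT level in KO1 (338 reads) and 1.46% in KO2 (1299 reads). The fall was -7.80 ± 0.05 log2 in KO1 and -5.98 ± 0.05 in KO2, with limma Benjamini-Hochberg adjusted p of 9.34e-08 and 1.80e-07. KRT17 was 4.63-fold higher in KO2 than in KO1 (adjusted p = 1.94e-04, limma with Benjamini-Hochberg adjustment). KRT17 has close paralogs and pseudogenes, and how shared reads were counted is not given in the sources used here, so the residual level is uncertain. It also lies in a stretch of chromosome 17, described below, where 73 of 85 tested protein-coding genes were lower and 9 higher. The fall of KRT17 therefore does not by itself show that the gene was edited.

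Among the genes fixed beforehand, E-cadherin fell and vimentin rose in both knockout groups. CDH1, the gene of the epithelial adhesion molecule E-cadherin, fell from 59.6 ± 1.49 FPKM in WT to 0.155 ± 0.00284 in KO1 and 0.494 ± 0.103 in KO2 (knockout average -5.53 ± 0.06 log2, limma Benjamini-Hochberg adjusted p = 1.91e-07). VIM, the mesenchymal intermediate filament gene, rose from 0.216 ± 0.128 to 39.0 ± 0.796 FPKM in KO1 and 40.9 ± 0.807 in KO2, 185-fold for the knockout mean. YAP1, the transcriptional coactivator of the Hippo pathway, was at 31.3 ± 0.610 FPKM in WT, 36.2 ± 0.725 in KO1 and 27.0 ± 0.660 in KO2. It was higher than WT in KO1 (0.21 ± 0.03 log2, limma adjusted p = 0.00223) and lower in KO2 (-0.20 ± 0.03, adjusted p = 0.00237), so the knockout average was not called (0.00 ± 0.03 log2, adjusted p = 0.954). Under quantile normalization, library size as the only scaling and voom, the call in KO2 was lost (adjusted p = 0.597, 0.25 and 0.245) and the average was called higher at 0.17, 0.15 and 0.15 log2. Its paralog WWTR1 (TAZ) fell 2.59-fold.

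IL6, the gene of the cytokine interleukin 6, had 0 reads in both WT libraries. It was at 5.75 ± 0.0164 FPKM in KO1 (548 reads) and 0.409 ± 0.195 in KO2 (32 reads), and the knockout mean was at least 42.2-fold above the WT floor. The limma adjusted p of its knockout average was 4.23e-05, and 0.123 when KO1 and KO2 were treated as one group of 4. The call of IL6 in KO2 was lost without WT replicate 1 or 2 (adjusted p = 0.0551 and 0.0549). The YAP target CCN2 fell 6.90-fold, from 5.06 ± 0.467 FPKM. ANKRD1, another such target, fell from 4.05 ± 0.164 FPKM to 1 read in KO1 and 0 in KO2. CCN1 was at 10.3 ± 0.509 FPKM in WT, not called in KO1 (0.17 ± 0.06 log2, limma adjusted p = 0.0523, but called higher in 7 alternatives) and lower in KO2 (-0.66 ± 0.06, adjusted p = 3.28e-04). The call for its knockout average (-0.24 ± 0.06 log2, adjusted p = 0.00969) was lost without WT replicate 1 (adjusted p = 0.0855), with library size as the only scaling (0.142), with voom (0.107), with one knockout group of 4 (0.503) and against a fold of 1.5. STAT3, the transcription factor downstream of IL6, rose in KO1 (0.30 ± 0.04 log2, limma adjusted p = 0.00168) and was not called in KO2 (0.09 ± 0.04, adjusted p = 0.107, but called higher in 4 alternatives). The call for its knockout average (0.19 ± 0.04) was lost with one group of 4 and against a fold of 1.5.

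**Figure D1:**
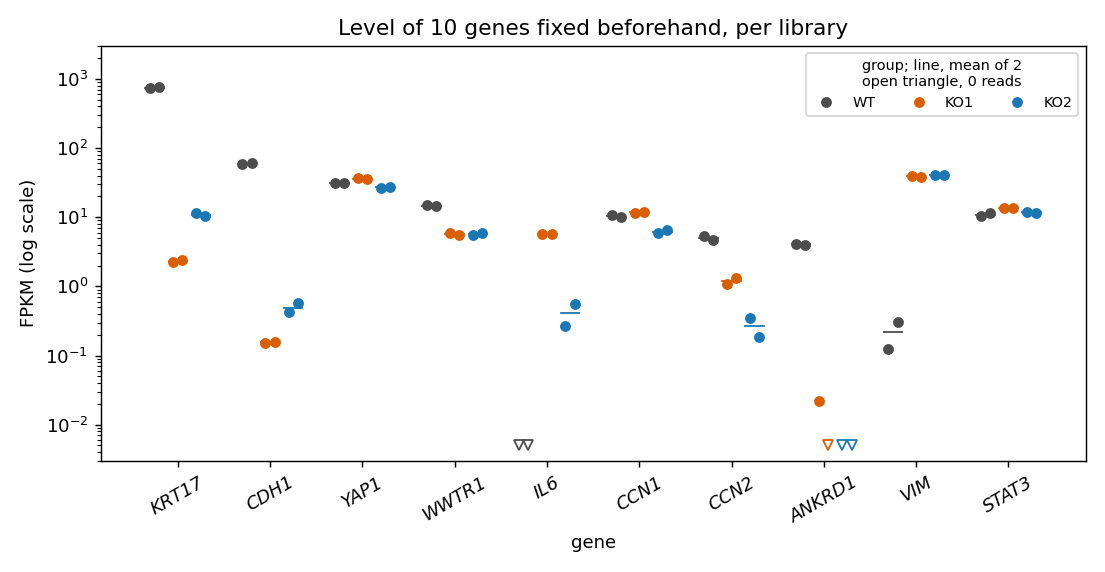
FPKM on a log scale of the 10 genes fixed beforehand, each point a library, each line the mean of the 2 libraries of a group, with open triangles at the bottom for 0 reads. KRT17 sits at 746 FPKM in WT against 2.35 and 10.9 in KO1 and KO2, and VIM at 0.216 against 39.0 and 40.9.

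Most tested genes differed between the knockout average and WT: 6498 were called higher and 6442 lower, which is 80.6% of 16046. Without a filter on values, 7788 were higher and 8802 lower, which is 45.9% of 36164. The balance depended on scaling, with 7435 higher and 5615 lower with library size as the only scaling and 7393 and 5826 with voom. Changes beyond 2-fold on the log2 scale were called for 2365 higher and 2344 lower genes. The highest fold change belonged to BASP1, a membrane-bound signalling protein gene, with 0 reads in WT and 442 ± 4.27 and 489 ± 3.11 FPKM in KO1 and KO2, at least 6830-fold above the floor. FOLR1, the folate receptor alpha gene, rose 190-fold to 1059 ± 12.9 and 738 ± 7.83 FPKM. CPS1, the mitochondrial enzyme gene that starts the urea cycle, rose 956-fold from 0.126 ± 0.00118 FPKM. Also among the 10 highest, COL5A1 rose 1210-fold to 114 FPKM, COL7A1 333-fold to 148, FBLN1 1940-fold to 85.6 and IGFBP7 1100-fold to 94.9. SRGN rose 226-fold and NPTX1 1500-fold. GAGE2A had 0 reads in WT and was at 83.5 ± 7.50 FPKM in the 4 knockout libraries, but it belongs to a family of near-identical copies and its level is uncertain.

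The lowest fold change belonged to KRT19, a keratin of simple epithelia, which fell from 1728 ± 47.4 FPKM (161100 reads) to 10 reads in KO1 and 0 in KO2 (-10.69 ± 0.05 log2, limma Benjamini-Hochberg adjusted p = 4.16e-08). KLK6, a secreted serine protease gene, fell from 341 ± 6.57 FPKM to 0 reads in all 4 knockout libraries, at least 4690-fold. ALDH1A1 fell from 263 ± 3.53 FPKM to 5 reads in KO1 and 2 in KO2, GPX2 1030-fold from 166 ± 4.42, ACTL8 690-fold from 156 ± 1.81 and LCN2 289-fold from 211 ± 1.51. BMP4 fell from 231 ± 5.01 FPKM to 3 reads in KO1 and 0 in KO2, and KRT23 from 191 ± 0.541 FPKM to 0 reads in KO1 and 1 in KO2. ERBB2 fell 250-fold, from 1387 ± 46.4 FPKM in WT to 5.82 ± 0.360 in KO1 and 5.29 ± 0.0233 in KO2.

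Genes beside ERBB2 were lower with it. Of 37 other tested protein-coding genes within 1 Mb of ERBB2 (chromosome 17, 39687914 to 39730426), 36 fell and 1 rose, with a median of -2.77 log2 and a range of -6.22 to 0.66. Their median level was 53.4 FPKM in WT and 6.69 in the knockout libraries, against 6.90 and 6.78 over 11852 protein-coding genes. The lowest median of 10000 random lists of that size was -0.73. The region was chosen after the fall of ERBB2 was seen. Random lists also draw genes from scattered positions, so this value describes the region and does not test it. GRB7, an adaptor gene next to ERBB2, fell 60.6-fold from 278 ± 8.29 FPKM. RPL23, a ribosomal protein gene, fell by 3.44 log2. RPL19 (ribosomal protein), PSMB3 (proteasome) and MED1 (Mediator), chosen after their values were seen, were at -3.40, -3.16 and -4.23 log2. The 25-gene windows beyond the shuffled 95th percentile ran from 36591798 to 42388568 and held 85 genes, 73 lower, 9 higher and 3 not called. That stretch also contains KRT17, KRT19, KRT20, KRT23, GAST, TOP2A and STAT3.

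Epithelial structural genes were lower in the knockout average. All 6 simple keratins fell (limma camera adjusted p = 0.00147, and adjusted p = 0.214 with an estimated correlation). KRT8 fell 6.34-fold from 1148 ± 16.1 FPKM, and KRT20 from 57.8 ± 3.66 FPKM to 4 reads in KO1 and 5 in KO2. Of 11 stratified keratins other than KRT17, 9 fell, 1 rose and 1 was not called (adjusted p = 0.00201 by camera; adjusted p = 0.214 with an estimated correlation). KRT4 and KRT6A, the latter with close paralogs and so uncertain, fell to 0 reads in all 4 knockout libraries, at least 643-fold and 471-fold. Of the simple list, KRT19, KRT20 and KRT23 lie in the stretch around ERBB2 described above. So do KRT13 and KRT15 of the stratified list, and KRT10, KRT14 and KRT16, which also fell. KRT8, KRT4 and KRT6A lie on another chromosome. The keratin lists were not tested without the genes of that stretch, so their camera results do not separate the lists from position. Of 23 adherens and tight junction genes, 21 fell and 2 rose (camera adjusted p = 5.40e-06; adjusted p = 0.214 with an estimated correlation). EPCAM, an epithelial adhesion gene, fell 62.3-fold from 186 ± 2.29 FPKM, CLDN4 9.25-fold and CLDN7 3.54-fold. Of 10 desmosome genes 8 fell and 2 rose (camera adjusted p = 0.0236; adjusted p = 0.214 with an estimated correlation). DSG3 fell at least 1170-fold to 0 reads and PKP2 fell 7.26-fold, while DSG2 rose 1.77-fold. The junction gene JUP, at -1.94 log2, also lies in the stretch around ERBB2. Matrix adhesion genes split, with 8 higher, 9 lower and 1 not called (camera adjusted p = 0.747): ITGA5 rose 6.27-fold and LAMB1 4.73-fold, and ITGB6 fell 149-fold.

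Mesenchymal genes rose on balance, 14 of 18 higher and 4 lower (limma camera adjusted p = 0.00201; adjusted p = 0.214 with an estimated correlation). CDH2, the gene of N-cadherin, rose from 2 reads in WT to 12.2 ± 0.323 FPKM (n = 4). SNAI2, a repressor of CDH1, rose from 0 reads to 10.1 ± 0.401 FPKM (n = 4), at least 228-fold. Of 6 fibroblast markers, 5 rose and 1 fell (camera adjusted p = 0.0236; adjusted p = 0.214 with an estimated correlation). LUM had 0 reads in WT and 29.6 ± 1.31 FPKM in the knockout libraries (n = 4), DCN had 1 read in WT and 7.37 ± 1.77 FPKM (n = 4), and COL1A1 rose 15.9-fold; COL1A1 is also in the mesenchymal list. The leukocyte and endothelial lists had 1 tested member each, both higher, and the neuroendocrine list 2, 1 higher and 1 lower, so none of the 3 was tested as a list.

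YAP/TAZ targets went both ways: 14 of 24 rose and 10 fell (limma camera adjusted p = 0.181). AXL, a receptor tyrosine kinase gene, rose 51.6-fold, FSTL1 17.4-fold and TEAD1, a partner of YAP1, 3.62-fold, against the falls of CCN2 and ANKRD1. Of 17 Hippo pathway genes 13 fell, 2 rose and 2 were not called (camera adjusted p = 0.0166; adjusted p = 0.253 with an estimated correlation). AMOT fell from 5.17 ± 0.0445 FPKM to 2 reads in each knockout group, and NF2 fell 2.69-fold. In the IL6/JAK/STAT3 list 12 of 19 rose, 5 fell and 2 were not called, and 13 rose when adjusted over the list alone (camera adjusted p = 0.0648). LIFR, the leukaemia inhibitory factor receptor gene, rose 51.0-fold to 20.9 ± 2.57 FPKM (n = 4), SOCS3 28.3-fold, PIM1 4.66-fold and OSMR 3.65-fold. LIFR and OSMR lie in the highest window of chromosome 5 (34915376 to 43043170), whose median was 1.68 log2, and TEAD1 and BASP1 also lie in stretches of higher windows. NF-kB and inflammatory genes split into 9 higher, 8 lower and 3 not called (camera adjusted p = 0.692), with IL32 up 16.8-fold and PTGS2 up 10.5-fold.

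Interferon response genes fell as a group: 24 of 25 were lower and 1 was not called, and 25 fell when adjusted over the list alone (limma camera adjusted p = 2.21e-07; adjusted p = 0.214 with an estimated correlation). IFI27 fell 318-fold from 110 ± 2.35 FPKM, OAS2 278-fold, MX1 112-fold and IFITM1 22.1-fold. Antigen presentation genes were 2 higher, 8 lower and 3 not called (camera adjusted p = 0.0648).

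Of 6 tested intestinal markers 5 fell and 1 rose (limma camera adjusted p = 0.0397; adjusted p = 0.239 with an estimated correlation). CDX2, the intestinal homeobox gene, fell from 24.9 ± 1.04 FPKM to 0 reads in KO1 and 1 in KO2, and VIL1 fell 94.4-fold. MUC13 rose 30-fold to 75.6 ± 2.72 FPKM (n = 4). Gastric lineage markers were 5 higher and 2 lower of 7 (camera adjusted p = 0.148), with PSCA up 8.83-fold, MUC1 up 7.10-fold and GAST, the gastrin gene, down 10.5-fold. Of 11 stem and progenitor markers 9 fell and 2 rose (camera adjusted p = 0.00593), and of 15 Wnt response genes 13 fell and 2 rose (camera adjusted p = 0.00135), each with an adjusted p = 0.214 with an estimated correlation. AXIN2, a feedback target of Wnt signalling, fell 223-fold from 82.8 ± 1.72 FPKM, ZNRF3 17.5-fold and WNT11 225-fold. TNFRSF19 fell at least 1490-fold to 0 reads, and WNT5A rose from 0 reads to 10.9 ± 1.77 FPKM (n = 4), at least 534-fold. Of 12 squamous differentiation genes 11 fell and 1 rose (camera adjusted p = 6.56e-04; adjusted p = 0.214 with an estimated correlation), IVL, the involucrin gene, at least 424-fold to 0 reads.

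In the ERBB list, 6 of 9 genes fell, 1 rose and 2 were not called (limma camera adjusted p = 0.0397; adjusted p = 0.237 with an estimated correlation), and ERBB2 and GRB7 lie in the 17q stretch described above. TGF-beta response genes were 7 higher and 12 lower (camera adjusted p = 0.264). ID3 rose 123-fold and BMP2 82.9-fold. Immediate early genes were 4 higher, 14 lower and 4 not called (camera adjusted p = 0.0648): EGR1 fell 19.8-fold from 162 ± 6.28 FPKM, and DUSP1 rose 31.7-fold to 194 ± 45.9 FPKM (n = 4).

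Of 22 hypoxia and glycolysis genes 16 rose, 5 fell and 1 was not called (limma camera adjusted p = 0.00503; adjusted p = 0.214 with an estimated correlation). NDRG1 rose 20.4-fold and LDHA, the lactate dehydrogenase gene, 3.91-fold, while SLC2A1, the glucose transporter gene, fell 4.91-fold. Cholesterol synthesis genes were 4 higher, 17 lower and 1 not called (camera adjusted p = 0.00916; adjusted p = 0.253 with an estimated correlation). FDFT1 fell 3.34-fold and SQLE 2.80-fold. G2/M genes were 5 higher, 15 lower and 3 not called (camera adjusted p = 0.0397; adjusted p = 0.272 with an estimated correlation). TOP2A, inside the 17q stretch, fell 2.50-fold and CDC20 2.49-fold. G1/S genes were 13 higher, 7 lower and 3 not called (camera adjusted p = 0.234), with MCM3 up 2.11-fold. Heat shock genes were 1 higher, 10 lower and 2 not called (camera adjusted p = 0.00916; adjusted p = 0.214 with an estimated correlation).

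Ribosomal protein genes were 4 higher, 19 lower and 5 not called (limma camera adjusted p = 0.0134; adjusted p = 0.564 with an estimated correlation). Mitochondrially encoded mRNAs were 1 higher, 8 lower and 4 not called (camera adjusted p = 0.0337; adjusted p = 0.359 with an estimated correlation), and MT-ND2, at -0.42 log2, turned to 0.10 under quantile normalization. Nuclear respiratory chain genes were 11 higher, 10 lower and 3 not called (camera adjusted p = 0.959). The p53 targets were 9 higher and 11 lower (camera adjusted p = 0.713), ATF4 and unfolded protein genes 11 higher, 6 lower and 2 not called (0.117), and xenobiotic genes 7 higher, 6 lower and 3 not called (0.807). Histone genes, uncertain because their copies share reads, were 13 higher, 1 lower and 1 not called (camera adjusted p = 0.00201; adjusted p = 0.214 with an estimated correlation). The highest window of chromosome 6 (26634383 to 29005316, median 1.16 log2) holds 3 of the 13 tested histone list members of that chromosome. Overlapping stretches of higher windows ran from 24544104 to 29681110 there, and the members inside them were not counted. Camera called 20 of 33 lists in this comparison, and 0 with an estimated correlation (smallest adjusted p = 0.214), where 4 had an unadjusted p under 0.05. For 34 of 36 lists the counts adjusted over the list alone equalled those over all genes, the exceptions being the IL6 and interferon lists.

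**Figure D2:**
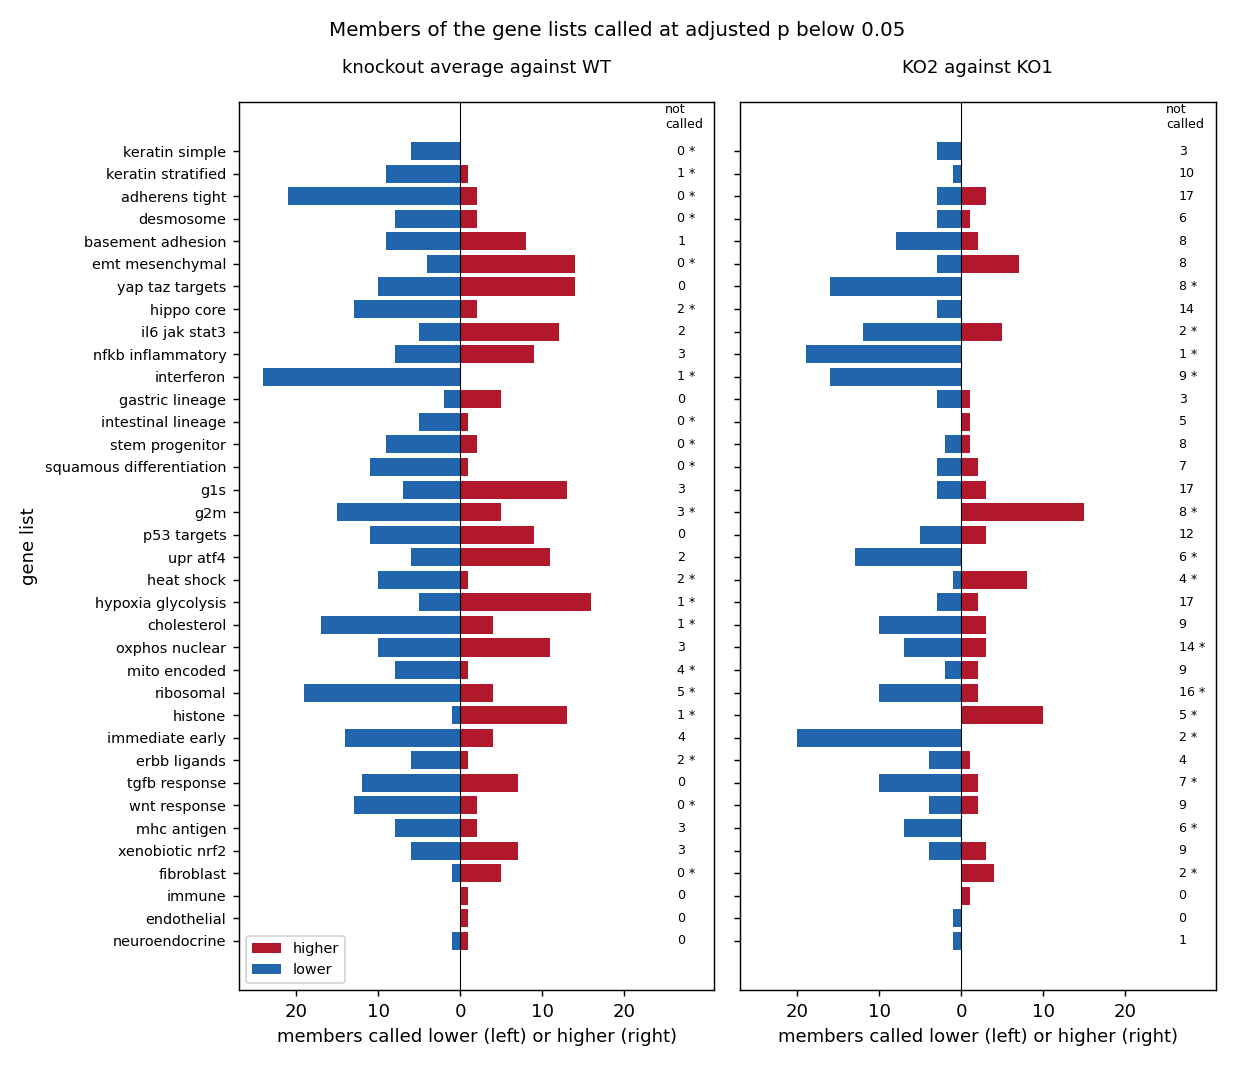
Members of each of the 36 gene lists called higher (right) or lower (left) by limma at an adjusted p below 0.05, with the number not called at the right edge and a star where camera called the list. The junction list has 21 lower and 2 higher members for the knockout average, and the NF-kB list has 19 lower members for KO2 against KO1.

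Compared with WT one at a time, both knockout groups showed the same broad picture. KO1 had 6299 genes higher and 6189 lower, and KO2 had 6274 higher and 6386 lower (limma, Benjamini-Hochberg). Both groups were higher for 5591 genes and lower for 5699, where independent lists would share 2463 and 2463 and unchanged groups simulated against the shared WT libraries shared 0. Opposite calls were made for 191 genes. Across genes, which are not independent replicates, the fold changes of KO1 and KO2 correlated at r = 0.965, against 0.50 for simulated unchanged groups, with a covariance of 1.48 against 0.0108, a difference of 1.47. Both comparisons, and the simulated ones, use the same 2 WT libraries. The simulation held no changed gene, so it covers noise only. With KO1 set against one WT replicate and KO2 against the other, a check chosen after the data were examined, r was 0.945 and 0.943. That split removes the noise of a shared library, but not a trait shared by both WT libraries.

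Camera called 22 lists for KO1 and 21 for KO2, 18 of them in both, and 0 in either with an estimated correlation (smallest adjusted p = 0.205 and 0.168, with 5 and 6 lists under an unadjusted p of 0.05). Called for KO1 and not for KO2 were YAP/TAZ targets (15 higher, 6 lower and 3 not called in KO1), the IL6 list (13 higher, 5 lower, 1 not called), ATF4 and unfolded protein genes (12 higher, 3 lower, 4 not called) and G2/M genes (4 higher, 18 lower, 1 not called). Called for KO2 and not for KO1 were the ERBB list (0 higher, 8 lower), immediate early genes (4 higher, 18 lower) and antigen presentation genes (1 higher, 11 lower). The direct test of KO2 against KO1 called all of these but the ERBB list (camera adjusted p = 0.0557). With an estimated correlation it called 0 lists (smallest adjusted p = 0.067).

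**Figure D3:**
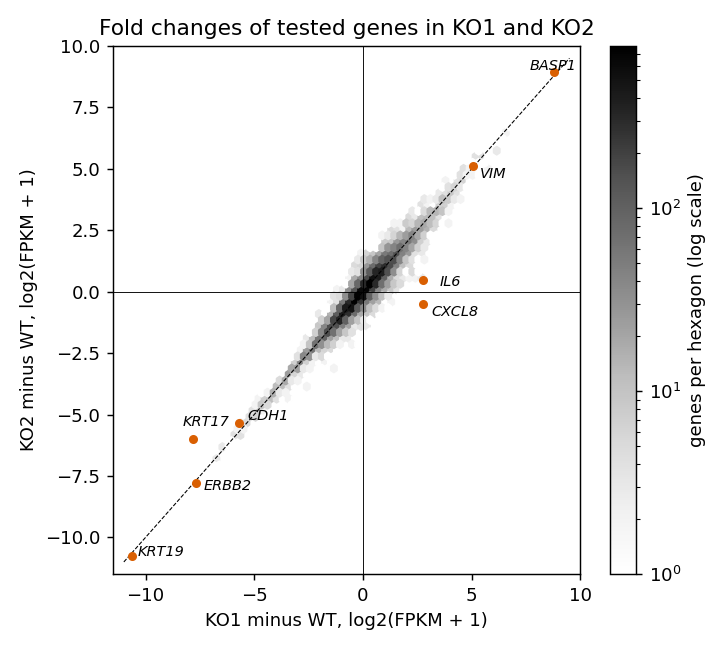
Fold change of KO1 minus WT (horizontal axis) against KO2 minus WT (vertical axis) on the log2(FPKM + 1) scale for tested genes, shaded by genes per hexagon, with the identity line dashed. The genes follow the line (r = 0.965), and KRT17, IL6 and CXCL8 lie off it.

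KO2 differed from KO1 in inflammatory and immediate early genes, among others. KO2 had 1800 genes higher and 2403 lower than KO1, of which 82 and 138 were beyond 2-fold. The excess of lower genes depended on scaling: 2148 were higher and 2108 lower with quantile normalization, 2084 and 2111 with library size as the only scaling, and 2725 and 2702 with voom. Of 20 NF-kB and inflammatory genes 19 were lower in KO2 and 1 was not called (limma camera adjusted p = 4.94e-13; adjusted p = 0.067 with an estimated correlation). CXCL8, the gene of the neutrophil chemokine interleukin 8, was at 25.9 ± 1.81 FPKM in KO1 and 1.81 ± 0.0773 in KO2, with 2.95 ± 0.208 in WT. ICAM1 was 3.08-fold and IL32 2.04-fold lower in KO2, and IL6, of the IL6 list, 14.1-fold lower. Of 22 immediate early genes 20 were lower in KO2 and 2 not called (camera adjusted p = 5.64e-12; adjusted p = 0.067 with an estimated correlation), EGR1 2.45-fold and DUSP1 1.51-fold.

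MUC5AC, the gastric surface mucin gene, was at 9.16 ± 0.537 FPKM in KO1, 0.176 ± 0.000371 in KO2 and 0.228 ± 0.000348 in WT. OLR1 was 11.5-fold lower in KO2. MAGEA1 (1285 reads in KO1, 44 in KO2) and MAGEA11 (883 reads against 3) were also lower, but they have related copies and are uncertain. Higher in KO2 were CGA, the common glycoprotein hormone alpha subunit gene, 14.9-fold to 5.39 ± 0.0527 FPKM, SORBS2 49.5-fold, OLFML1 12.9-fold, PKDCC 14-fold and KRT17.

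Of 24 YAP/TAZ targets 16 were lower in KO2, 0 higher and 8 not called, and 16 lower and 1 higher when adjusted over the list alone (limma camera adjusted p = 1.58e-05; adjusted p = 0.135 with an estimated correlation). CCN2 was 4.5-fold, CCN1 1.90-fold and YAP1 1.34-fold lower in KO2. YAP1 lies in a stretch of chromosome 11 (78068304 to 116788050) where 62 of 99 genes were lower and 3 higher, and its difference of -0.41 log2 is close to the lowest window median there (-0.41). Interferon genes were 16 lower and 9 not called, 17 lower when adjusted over the list alone (camera adjusted p = 5.86e-07; adjusted p = 0.135 with an estimated correlation). ATF4 and unfolded protein genes were 13 lower and 6 not called, 14 lower and 1 higher when adjusted over the list alone (camera adjusted p = 1.54e-05; adjusted p = 0.135 with an estimated correlation). Antigen presentation genes were 7 lower and 6 not called, 8 lower when adjusted over the list alone (camera adjusted p = 0.00215; adjusted p = 0.144 with an estimated correlation). The IL6 list was 5 higher, 12 lower and 2 not called (camera adjusted p = 0.0460; adjusted p = 0.386 with an estimated correlation), with OSMR 1.82-fold lower and SOCS3 1.47-fold higher. TGF-beta response genes were 2 higher, 10 lower and 7 not called (camera adjusted p = 0.0347; adjusted p = 0.286 with an estimated correlation).

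Other lists were called in both directions. G2/M genes were 15 higher in KO2 and 8 not called, 17 higher and 1 lower when adjusted over the list alone (limma camera adjusted p = 5.94e-07; adjusted p = 0.135 with an estimated correlation), with CDC20 1.21-fold and TOP2A 1.18-fold higher. Heat shock genes were 8 higher, 1 lower and 4 not called (camera adjusted p = 0.00748; adjusted p = 0.159 with an estimated correlation). Fibroblast markers were 4 higher and 2 not called (camera adjusted p = 0.00438; adjusted p = 0.159 with an estimated correlation), with COL1A1 1.69-fold and DCN 1.52-fold higher. Histone genes, uncertain as above, were 10 higher and 5 not called, 12 higher when adjusted over the list alone (camera adjusted p = 1.93e-06; adjusted p = 0.135 with an estimated correlation). The highest window of chromosome 6 (26199520 to 27811300, median 0.56 log2) holds 7 of the 13 tested members of that chromosome. Here too overlapping stretches were wider, from 24544104 to 28159472, and the members inside them were not counted. Ribosomal genes were 2 higher, 10 lower and 16 not called (camera adjusted p = 0.0347; adjusted p = 0.750 with an estimated correlation), and nuclear respiratory chain genes 3 higher, 7 lower and 14 not called (0.0460; adjusted p = 0.523 with an estimated correlation). Each of these last lists had 12 lower when adjusted over the list alone. The other 19 tested lists were not called.

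Part of the difference between KO2 and KO1 followed position. On chromosome 1 the windows of neighbouring genes rose to a median of 0.94 log2 between 167721192 and 173858808, beyond the highest of 1000 shuffles (0.31). Chromosome 1 had 8 stretches of windows beyond the shuffled 95th percentile, all higher in KO2. Some of them overlap, so they are not 8 separate regions. The stretch with the highest median (161039251 to 181061938) held 78 genes with an overall median of 0.40 log2, 58 higher and 2 lower, and the stretch from 150067279 to 156800817 held 145, 107 higher and 3 lower. The 8 together held 345 genes, each counted once, 219 higher and 14 lower. On chromosome 13 a stretch from 19633681 to 98577940 held 152 genes, 114 lower and 0 higher, on chromosome 9 one from 128683424 to 137870016 held 135, 87 lower and 5 higher, and on chromosome X one from 56729241 to 134797232 held 140, 94 higher and 3 lower. Over all chromosomes, stretches of higher windows held 7.34% of the scanned genes and 34.3% of those called higher, MUC1 and SOCS3 among them, and stretches of lower windows held 4.45% and 16.4% of those called lower. For the knockout average against WT the shares were 4.48% and 9.38% (higher), and 2.76% and 5.14% (lower). The same differences defined the stretches, so raised counts and shares of calls inside them follow by construction. Such windows lay on 7 of 23 chromosomes for KO2 against KO1 and on 9 for the knockout average against WT, against 0, 1 and 0 between the replicates of WT, KO1 and KO2.

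**Figure D4:**
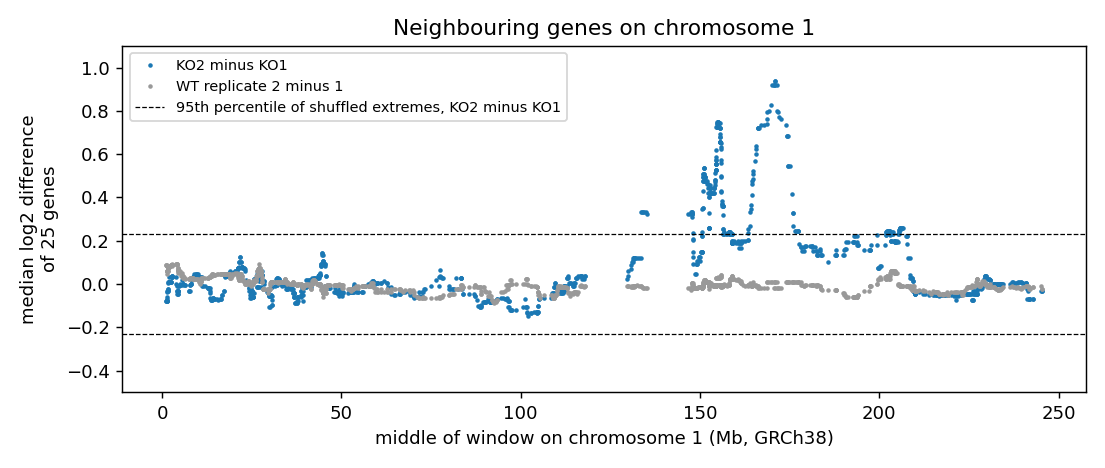
Median log2 difference of 25 neighbouring protein-coding genes along chromosome 1 in Mb of GRCh38 for KO2 minus KO1 (blue) and for WT replicate 2 minus 1 (grey), with dashed lines at the shuffled 95th percentile. KO2 minus KO1 reaches 0.94 on the long arm, and the WT replicates stay near 0.

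The counts of KO2 against KO1 rested on few libraries: without KO1 replicate 1 they were 833 higher and 1016 lower, and without KO1 replicate 2, 837 and 1134. Against a fold of 1.5 they were 41 higher and 88 lower, and the counts for the knockout average 3068 higher and 3201 lower.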

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

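The values in this part stood out because the difference between KO2 and KO1, which the labels give the same knockout, passed the limma test (genes) or limma camera (lists) at a Benjamini-Hochberg adjusted p below 0.05. Values are log2 differences of KO2 minus KO1. Among genes fixed beforehand they were 1.82 for KRT17, 0.37 for CDH1, -0.41 for YAP1, -2.27 for IL6, -0.83 for CCN1, -0.80 for CCN2 and -0.21 for STAT3. Among the widest differences from WT they were 0.15 for BASP1, -0.52 for FOLR1, 0.27 for CPS1, -0.19 for COL5A1, -0.59 for COL7A1, 0.24 for FBLN1, -0.56 for NPTX1 and -0.42 for LCN2. The widest differences between KO2 and KO1 were 2.23 for CGA, 1.92 for SORBS2, 1.84 for OLFML1, 1.79 for PKDCC, -3.38 for MAGEA1, -3.26 for CXCL8, -3.11 for MUC5AC, -2.78 for OLR1 and -2.68 for MAGEA11.

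Among list members, epithelial genes differed by -0.24 for KRT8, -0.15 for CLDN4, -0.12 for CLDN7 and -0.41 for PKP2, and matrix and mesenchymal genes by -0.22 for LAMB1, 0.53 for DCN and 0.70 for COL1A1. YAP/TAZ targets differed by -0.63 for FSTL1, -0.30 for AXL and -0.12 for TEAD1. Cytokine and inflammatory genes differed by 0.29 for LIFR, -0.38 for PIM1, 0.55 for SOCS3, -0.84 for OSMR, -1.0 for IL32, -0.23 for PTGS2, -1.43 for ICAM1, -0.32 for IFITM1 and -0.47 for IFI27. Lineage and Wnt genes differed by 0.64 for MUC1, -0.70 for GAST, 0.33 for ZNRF3 and -0.37 for WNT5A. Others were 0.27 for CDC20, 0.24 for TOP2A, -0.30 for FDFT1, -0.46 for SQLE, -0.59 for DUSP1 and -1.14 for EGR1.

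The medians of lists that camera called at its preset correlation were -0.45 for YAP/TAZ targets, -0.38 for the IL6 list, -1.06 for NF-kB, -0.32 for interferon, -0.49 for ATF4 and unfolded protein genes, -0.13 for the nuclear respiratory chain, -0.10 for ribosomal genes, -0.67 for immediate early genes, -0.20 for TGF-beta response and -0.28 for antigen presentation. They were 0.23 for G2/M, 0.23 for heat shock, 0.64 for histones and 0.37 for fibroblast markers. With an estimated correlation camera called 0 of these lists (smallest adjusted p = 0.067).

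Tests of KRT14 and KRT16 reads, of length and mean level and of a single library were written before their result was seen. The other tests that follow were written after. Most tested genes differed between WT and both knockout groups. With library size as the only scaling 13050 genes were still called, 2738 higher and 1990 lower beyond 2-fold. The scale factor in the FPKM values alone therefore did not account for this. A count of calls cannot exclude scaling as a source of small changes, and the balance of higher and lower calls moved with it. Some of the change followed position, with a window beyond the shuffled limit on 9 of 23 chromosomes. Stretches of such windows held 9.38% of the scanned genes called higher and 5.14% of those called lower (4.48% and 2.76% of all scanned genes). These shares are raised by construction, since the same fold changes defined the stretches, and change gene by gene stays open. Ribosomal, proteasome and Mediator genes near ERBB2 differed by a median of -3.07 log2 from their partners elsewhere; they were taken from a region already seen to fall, so a loss of extra 17q12 copies was not tested and stays open. Another source of cells than the WT culture stays open. Of protein-coding genes, 44 had 0 reads in WT and at least 5 FPKM in all knockout libraries, and 41 showed the reverse. Between KO1 and KO2 there were 0 such genes in either direction. A mark of more than 50 was set for the first count only, and after the data were examined. Falling short of it therefore does not argue against another source. Source and group cannot be separated here. An effect of KRT17 loss itself was not tested and stays open as well.

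KRT17 reads remained in both knockout groups, more in KO2. WT material carried over did not account for them, since KRT19, higher than KRT17 in WT, kept 0.00542% of its level in KO1 where KRT17 kept 0.314%. Reads of KRT14 or KRT16 assigned to KRT17 stay open, with KRT16 at 0.443 of the KRT17 level in KO1. In KO2 KRT16 was at 0.868 FPKM against 10.9 for KRT17, and KRT14 had 1 read, so neither rose with the higher KRT17 level there. An edited transcript that is still made was not tested.

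KO2 differed from KO1 in many genes. Gene length or mean level did not account for it (Spearman rho of 0.013 and -0.086 with the log2 difference). Sequencing depth was not tested. The KO2 libraries were shallower, with 18627054 and 17599759 recovered reads against 22673871 and 21880796 in KO1. All 19 NF-kB genes called lower had both KO2 libraries below both KO1 libraries, which excludes nothing because the call itself selects that order, but the median of the whole list stayed at -1.08 to -1.03 with any KO1 or KO2 library left out. The window median of 0.94 on chromosome 1, in a stretch with an overall median of 0.40, prompted the idea of a gain of part of 1q in KO2 and does not test it, so it stays open, as do the stretches on other chromosomes. Whether KO2 and KO1 stand for guides or clones is not given, so the origin of the other differences stays open.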

How the results depend on the processing

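The KRT17 fold changes kept their direction and size in every alternative: -7.17 to -6.64 log2 for the knockout average. With a filter of 5 FPKM, which tests fewer genes by construction, 3900 genes were higher in the knockout average, 3898 in KO1, 3801 in KO2 and 3495 in both. With that filter 4368 were lower in the knockout average, 4244 in KO1 and 4393 in KO2, so lower calls outnumbered higher ones. A test against a fold of 1.5, stricter by construction, left 3068 higher and 3201 lower for the knockout average, 2950 and 3023 for KO1, 2989 and 3206 for KO2, 41 and 88 for KO2 against KO1, and 2481 and 2741 in both knockout groups. With voom 2725 genes were higher in KO2 than in KO1; the cause was not tested. With 1 library left out, KO2 against KO1 gave 833 to 1502 genes higher and 1016 to 1863 lower, lowest without KO1 replicate 1 and highest without WT replicate 2. Those runs estimate the spread from fewer libraries by construction.

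With the replicate block the counts were 6470 higher and 6387 lower for the knockout average, and 1482 and 1985 for KO2 against KO1. The replicate numbers showed no pairing: the differences of replicate 2 minus 1 correlated across genes at 0.02 (WT and KO1), 0.00 (WT and KO2) and -0.04 (KO1 and KO2). The count test that the design named first was not run, since the deposited values are FPKM, and voom on the recovered reads was the only test on reads.

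Among named genes, 5 of 147 results for the knockout average changed in some alternative. They were YAP1, IL6, CCN1 and STAT3, described above, and MT-ND2, which reversed to 0.10 under quantile normalization (adjusted p = 0.0305). For KO2 against KO1, 39 of 52 results were lost against a fold of 1.5, and 16 in another alternative, CLDN4 and CLDN7 in 12 each, TEAD1 in 11, PTGS2 in 7 and CDH1 in 4. KO1 and KO2 against WT were recomputed for the genes fixed beforehand only, and 3 of 9 and 4 of 9 changed. Among lists, 23 of 66 results changed, with 42 calls lost and 23 gained. Gained calls for the knockout average included YAP/TAZ targets and the IL6 list without a filter (camera adjusted p = 0.0420 and 0.0178). For KO2 against KO1, gains included the ERBB list with quantile normalization, the filter of 5 FPKM and voom (camera adjusted p = 0.0442, 0.0353 and 0.0235). For the knockout average, the calls of desmosome and Hippo genes were lost with the filter of 5 FPKM (adjusted p = 0.0926 each), that of ribosomal genes with quantile normalization (0.154) and that of fibroblast markers with voom (0.0844). Calls of G2/M, mitochondrially encoded, intestinal and ERBB genes were each lost in 3 or more alternatives. For KO2 against KO1, the IL6 list was lost without either WT replicate (0.0637), and it, the nuclear respiratory chain, ribosomal and TGF-beta lists were each lost in 4 or more alternatives. Camera with an estimated correlation called 0 lists for the knockout average, 0 for KO1, 0 for KO2 and 0 for KO2 against KO1, and fry called 32 for the knockout average, 32 for KO2 and 24 for KO2 against KO1. Fry tests each list by itself, and camera against the other genes. The medians of matrix adhesion (-0.10) and nuclear respiratory chain genes (-0.06) for the knockout average changed sign with library size as the only scaling, to 0.05 and 0.09.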

Other observations

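Some genes were detected only in the WT or only in the knockout libraries, a group chosen after the data were examined. Of 19864 protein-coding genes, 44 had 0 reads in both WT libraries and at least 5 FPKM in all 4 knockout libraries, and 41 showed the reverse. Between KO1 and KO2 there were 0 such genes in either direction. BASP1 and KLK6, described above, are examples.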
